A study of Rattus norvegicus with 36 samples.

How the data were processed

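RNA of rat skeletal muscle was hybridised to 36 one-colour oligonucleotide arrays of 8799 probe sets. The source label gives the muscle only as "ta", which is left as written. Per the labels, the arrays fall into 6 groups by collection time after resisted contractions and by RNA fraction, total RNA or RNA on polyribosomes (polysomal RNA, the transcripts loaded with several ribosomes). Each group holds numbers 1 and 2, or 1 to 4, and each number has 2 arrays.

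The values used were intensity signals that the authors deposited in a table of all arrays, 1 value per probe set and array on a linear scale. The software, background correction and summary method were not given in the sources used here. The deposited values were already scaled: the 2% trimmed mean of an array ran from 801 to 801.9, with medians of 148.5 to 266.3. That scaling was kept, because the trimmed means lay within the 10% tolerance set in advance. The direction and linear scale follow from the values, whereas the target of the scaling and any centring step before it stay unknown.

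After 59 control probe sets were left out, 8740 remained. Signals below the 40th percentile of all values, 129.5, were set to that floor, log2 was taken, and the 6707 probe sets above the floor on at least 4 arrays were tested. The 2 arrays of a number were averaged to 1 replicate, because the titles do not say whether they came from separate muscles. The labels do not say either whether numbers are separate animals. The p-values therefore measure only the spread between these samples, which may be technical. Between the arrays of a number the correlation over probe sets ran from 0.897 to 0.981, and over the 612 other pairs of arrays from 0.775 to 0.975, so no array was a copy of another. The 18 replicates, and with them the number of arrays, limit the precision.

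Gene symbols came from the platform annotation of the series, updated through Entrez identifiers with a table of current rat genes. Of the 8740 probe sets 7006 had 1 symbol, 308 several and 1426 none, and 6985 symbols were found or updated through the Entrez identifier. Probe sets with several symbols or none were not named. The 3903 tested genes were each represented by their brightest probe set, and 1152 of them had more than 1 tested probe set. No genome build was named, so no coordinates are given.

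All comparisons were contrasts of 1 model over the 6 groups, fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes) in R 4.3.3, without covariates, two-sided, with Benjamini-Hochberg adjustment over the 6707 probe sets and a threshold of 0.05. The fit had 12 residual degrees of freedom. The 6 h polysomal group was set against the polysomal control, and the 1 h polysomal group against the control titled 1hr polysome. Polysomal was set against total RNA at each time, 6 h against 1 h within each fraction, both controls against each other, and 1 h total RNA against the control titled 1hr polysome. The change of the fraction difference and of the polysomal response between 1 h and 6 h were tested as differences of contrasts. No array of uncontracted muscle has total RNA in both title and description, so the 6 h total group had no control of its own fraction. A group mean whose arrays all lay at the floor gave only a bound, and the fold is then given as "at least", from the mean of the bright group over the floor.

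Samples, comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined, and the alternatives as well except those marked below. The rule named, for the first 6 comparisons, the 12 highest and the 12 lowest called genes measured above the floor in both groups, and from each list the called member with the largest change. For the remaining 4 comparisons it named the 3 highest and the 3 lowest. Where fewer than 5 genes were called, the 5 with the smallest p were given as not passing. Of the immediate early genes, growth regulators and cell markers, the members with the smallest p could also be named. Other members of lists named below were chosen after their values were seen.

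The 24 lists covered immediate early genes, muscle growth and myogenic regulators, heat shock and protein folding, antioxidant proteins and metallothioneins, inflammation and chemokines, fuel use and angiogenesis regulators, proteolysis, polyamine metabolism, cytosolic ribosomal proteins, translation factors, other terminal oligopyrimidine mRNAs, the nuclear-encoded mitochondrial respiratory chain, glycolysis and glycogen, fast and slow fibre sarcomere and calcium handling, extracellular matrix, and markers of macrophages, neutrophils, red cells, adipocytes, endothelium with smooth muscle, and nerve with Schwann cells. Lists of iron-responsive element mRNAs (3 tested genes) and of long noncoding and nuclear RNAs (2 tested genes) fell short of the minimum of 4 and were not tested. The 22 others were tested against the remaining genes with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. A correlation estimated per list and fry, which asks whether the genes of a list move on balance one way, were run beside it.

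Whether equal numbers pair samples was checked through the correlation of their deviations from group means, with the pairing taken from the numbers in the titles. In polysomal RNA of the 6 h set, every number of the exercised group correlated best with the same number of the polysomal control, from 0.43 to 0.54. The mean of -0.16 for different numbers adds nothing, because deviations from a group mean cancel out. Between 6 h total RNA and the polysomal control the range was -0.03 to 0.25, and 1 of 4 numbers correlated best with its own. Equal numbers thus share something in polysomal RNA, but whether a sample or a processing step is not known.

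The alternatives chosen beforehand were floors at the 20th and 60th percentile, no filter on dim probe sets, quantile normalization, scaling to the 75th percentile, arrays entered singly with the number as a random block, only the groups of a comparison in the fit, a variance trend with robust estimation, the number as a replicate block, the other control or both controls, each number left out in turn, and for the lists the estimated correlation and all probe sets of a gene. Chosen after seeing the data were the runs without array 2bA of the control titled 1hr polysome, without array 1bA of the 6 h total group, without numbers 3 and 4 of that group, with numbers 1 and 2 or 3 and 4 of the 6 h set alone, without the arrays named 1A and 2A, and without probe sets above 20000 on any array. The lists were also rerun, a choice made after seeing the data, under both scalings, under the replicate block, and, for comparisons that hold them, without array 2bA, without array 1bA, without numbers 3 and 4 of the 6 h total group and without each 1 h polysomal number. Random blocks were estimated with statmod 1.5.0.

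The fit was tested on simulated data drawn from the real means and spreads of the 6707 probe sets, with known changes in 67 probe sets at 2-fold, 67 at 4-fold and 66 at 8-fold. In the comparison of 6 h polysomal RNA with its control, 56.7% of 2-fold, 95.5% of 4-fold and 97% of 8-fold changes were recovered, with 13 false calls. At 1 h, with 2 numbers per group, 28.4%, 77.6% and 89.4% were recovered in the comparison of polysomal RNA with its control. The simulated values were independent and normal, and the floor was not applied to them. They held no correlation between genes or between equal numbers. The shares therefore hold for such data and may overstate recovery on the real arrays, above all for dim probe sets.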

Results

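The series profiled the response of rat muscle to an acute bout of resisted contractions on 36 arrays. Muscle was collected 1 h or 6 h after the contractions, and total RNA or polysomal RNA was hybridised. Exercised muscle gave 4 arrays of total and 4 of polysomal RNA at 1 h (2 numbers each), and 8 of total and 8 of polysomal RNA at 6 h (4 numbers each). Of muscle whose labels name no contractions, 8 arrays (4 numbers) are polysomal in both title and description and are called the polysomal control. The other 4 (2 numbers) are titled 1hr polysome, while their description names no polysomes, and are called the control titled 1hr polysome. Both descriptions of control muscle give 1 h. On a typical array 40.05% of the values lay at the floor, and at most 142 probe sets of an array exceeded a signal of 20000.

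Polysomal RNA 6 h after the contractions was first set against the polysomal control, which asks which transcripts on ribosomes differed from uncontracted muscle. The descriptions give 6 h for the former and 1 h for the latter. The titles of the control give no time, and its array names are those of the 6 h groups. If its description holds, collection time differs along with contraction. Hspa1a, which encodes an inducible heat shock protein, rose 30.2-fold, from a geometric mean signal of 641 to 19400 (log2 means 9.32 ± 0.29 and 14.24 ± 0.45, SD, n = 4 numbers each; adjusted p = 0.000631). The stress-induced transcription factor Atf3 rose by 4.71 on the log2 scale (SE 0.64, adjusted p = 0.00385), and Ankrd1, a stretch-responsive ankyrin repeat protein of the sarcomere, by 4.52 (SE 0.84, adjusted p = 0.0333), from a signal of 1150 to 26300. Fos, a subunit of the AP-1 transcription factor, rose 7.66-fold (log2 2.94, SE 0.58, adjusted p = 0.043). All 3 of its probe sets had this direction, but only 1 of them passed. The adhesion receptor Pvr lay at the floor on every array of the control and was at least 16.8-fold higher after exercise (adjusted p = 0.0154).

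In all, 23 probe sets changed, 22 of them higher, and the 15 genes called by their brightest probe set all rose. With equal numbers as a block there were 33 calls, with 22 of the 23 among them. The control titled 1hr polysome as the control gave 16 (12 higher, 4 lower), with 8 of the 23 among them. Hbegf, a ligand of the EGF receptor, rose by 3.11 (SE 0.46), and Errfi1, a feedback inhibitor of that receptor, by 1.87 (SE 0.32; 2 of its 3 probe sets had this direction). Plaur, the urokinase receptor, rose by 2.74 (SE 0.43) and Cd44, the hyaluronan receptor, by 1.96 (SE 0.32; its other probe set had the opposite direction). The lipid droplet coat protein Plin2 rose by 2.65 (SE 0.48), the Z disc protein filamin C (Flnc) by 2.11 (SE 0.41), the transcription factor Runx1 by 2.11 (SE 0.40) and the ribosome rescue factor Pelo by 2.08 (SE 0.32). Adjusted p for these 8 genes ran from 0.00821 for Hbegf to 0.043 for Flnc. The remaining called genes were Pdpn at 1.82 and Prm3 at 1.29, and the 1 probe set that fell, by 1.16, has no symbol; all 3 were named after their values were seen.

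Of the 28 measured immediate early genes 2 rose (Atf3 and Fos), and 8 did when adjusted over the list alone; as a group they ranked above the remaining genes (camera adjusted p = 4.55e-11; adjusted p = 0.0755 with an estimated correlation). Egr1 (log2 2.77, SE 0.65, adjusted p = 0.113) and Nr4a3 (1.89, SE 0.45, adjusted p = 0.123), transcription factors of this group, did not pass. Of 30 growth and myogenic regulators 2 rose (Ankrd1 and Runx1), 5 when adjusted over the list alone, and the group ranked higher (adjusted p = 0.000215; 0.0755 as adjusted p with an estimated correlation); the muscle LIM protein Csrp3 stood at 2.21 (SE 0.51, adjusted p = 0.104). Of 28 inflammation and chemokine genes 2 rose (Plaur and Cd44), 5 over the list alone, with the group higher at adjusted p = 1.13e-05, against adjusted p = 0.0755 with an estimated correlation. Ccl2, which attracts monocytes, stood at 2.66 with an SE of 0.84 and did not pass (adjusted p = 0.342). Of 22 heat shock and folding genes 1 rose, Hspa1a, and 2 did when adjusted over the list alone (group adjusted p = 0.000803; adjusted p = 0.0803 with an estimated correlation); the cochaperone Dnaja1 stood at 2.07 (adjusted p = 0.16), while a dimmer probe set of it passed at 3.13.

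None of the 15 macrophage markers passed limma's test by itself, or over the list alone, and Lgals3 stood at 1.11 (SE 0.38) and Lyz2 at 1.4 (SE 0.55). As a group they ranked higher (adjusted p = 0.00387; adjusted p = 0.145 with an estimated correlation). None of the 4 neutrophil markers changed (S100a8 0.62, SE 0.59; group adjusted p = 0.423). Markers of nerve with Schwann cells (adjusted p = 0.282), adipocytes (0.865), red cells (0.916) and endothelium with smooth muscle (0.916) did not rank apart either. The 4 polyamine genes ranked higher (adjusted p = 0.0329; adjusted p = 0.0926 with an estimated correlation), although none passed by itself and 1 did over the list alone; after quantile normalization they did not pass (0.0563; range over 5 alternatives 0.0262 to 0.0926). The 39 ribosomal protein genes ranked higher by a median of 0.12 above all genes, and the 34 proteolysis genes lower by a median of -0.16. Both stood at adjusted p = 0.0446, and at adjusted p = 0.564 with an estimated correlation. The ribosomal result did not pass after quantile normalization (0.118) or with the 75th percentile (0.0588), and its adjusted p over 5 alternatives ran from 0.0165 to 0.564. The proteolysis result did not pass with the 75th percentile (0.0588; range over 5 alternatives 0.0226 to 0.564). Translation factors (adjusted p = 0.77) and other terminal oligopyrimidine mRNAs (0.0672) did not pass.

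The 15 called genes kept their direction in all alternatives, but not their calls. Hspa1a passed in 21 of 23 and Atf3 in 20 of 23. Ankrd1 passed in 11 of 23 (adjusted p up to 0.937), Flnc in 11 of 23 and Fos in 9 of 23 (up to 0.927). Runx1 passed in 9 of 24, Prm3 in 8 of 24 and Pdpn in 6 of 24. Within numbers 1 and 2 and within numbers 3 and 4 of the 6 h set, 1 and 0 probe sets were called by limma (341 and 424 had an unadjusted p under 0.05). The median absolute log2 change of the 23 was 2.69 and 2.85 there, for probe sets chosen on all 4 numbers. Over all probe sets, which are not independent replicates, the changes in both pairs of numbers correlated at 0.618. The count moved when numbers were left out: it was 11, 14, 8 and 9 without numbers 1 to 4 of the control in turn, and 9, 38, 13 and 7 without numbers 1 to 4 of the exercised group.

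**Figure D1:**
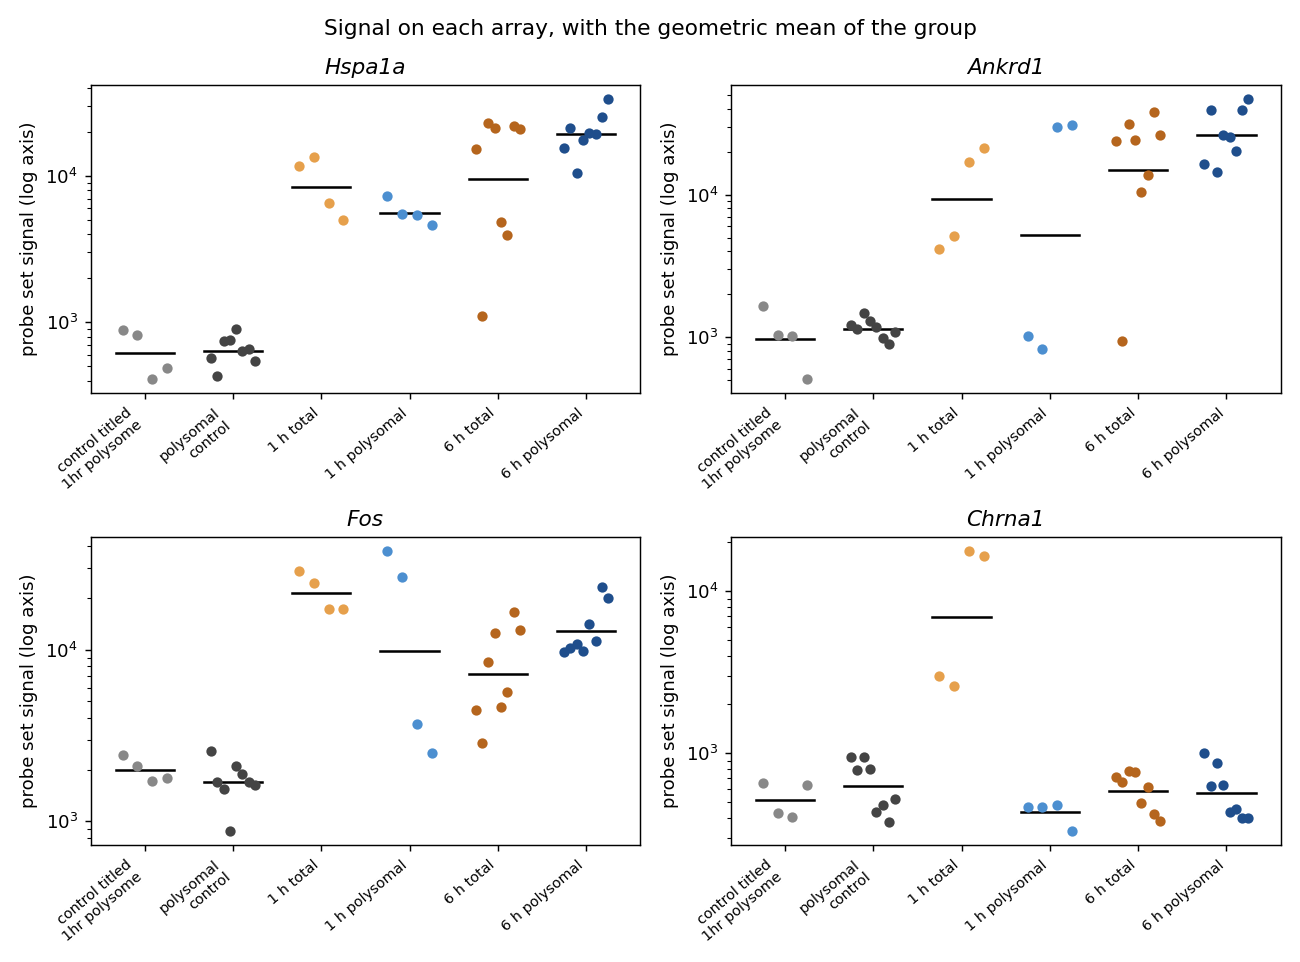
Signal (log axis) of Hspa1a, Ankrd1, Fos and Chrna1 on each of the 36 arrays, by group, with a bar at the geometric mean of the group. Hspa1a averaged 641 in the polysomal control and 19400 in polysomal RNA at 6 h, while Chrna1 reached 6910 on average in total RNA at 1 h alone and 431 to 627 in the other groups.

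At 1 h, polysomal RNA of exercised muscle was set against the control titled 1hr polysome, with 2 numbers each. The log2 change of Hspa1a was 3.19 (SE 0.72), of Egr1 3.22 (SE 0.92), of Klf6, a zinc finger transcription factor, 2.20 (SE 0.69) and of the AP-1 subunit Junb 2.10 (SE 0.68). None of these passed, with adjusted p from 0.646 for Hspa1a to 0.99 for Klf6 and Junb. No probe set passed limma's test, with 299 at an unadjusted p under 0.05 where chance gives 335. Besides Hspa1a, the smallest p-values belonged to Tom1l2 (-1.07, SE 0.24), Hsd11b1 (1.12, SE 0.26), Kif13a (-1.37, SE 0.32) and the annexin partner S100a10 (1.76, SE 0.42), all at adjusted p = 0.646.

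The exercised numbers differed from each other at 1 h. Ankrd1 had signals of 1010 and 818 on the arrays of number 1 and of 29800 and 30700 on those of number 2, whereas Fos had 37800 and 26500 on number 1 and 3710 and 2510 on number 2. Without number 1 of the exercised group 46 probe sets were called, and without number 2 there were 2.

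All 22 probe sets raised at 6 h were also above 0 at 1 h, on other arrays, with a median of 1.66 against 2.83, and 12 of them had an unadjusted p under 0.05. The middle of all probe sets lay at -0.028 at 1 h. The 22 were chosen on their 6 h values, so these medians do not compare the size of the responses. In total RNA at 1 h 21 of the 22 were above 0 with a median of 1.56, where all probe sets had 0.03. That comparison uses the same control arrays, so it is not separate support. Runx1 stood at 0.10 (SE 0.56) in polysomal RNA at 1 h, 2.01 less than at 6 h, a difference that did not pass (adjusted p = 1). The arrays of number 2 at 1 h differed in Runx1, with signals of 302 and 3270 against 657 to 1320 in the control.

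Among the gene lists at 1 h, none of the 31 matrix genes passed by itself or over the list alone, but the list ranked higher (median 0.42 above all genes, adjusted p = 4.32e-05; adjusted p = 0.0899 with an estimated correlation). Mgp, the matrix Gla protein, stood at 1.05 (SE 0.36) and the collagen crosslinking enzyme Lox at 1.62 (SE 0.64); against the polysomal control as an alternative they were at -0.27 and -0.28. The 10 slow fibre genes ranked lower (median -0.88 below all genes, adjusted p = 0.000119; adjusted p = 0.0535 with an estimated correlation), with none passing by itself and 5 over the list alone. Among them, the slow myosin heavy chain Myh7 stood at -1.15 (SE 0.39) and the slow myosin light chain Myl2 at -1.26 (SE 0.44). Immediate early genes ranked higher (adjusted p = 0.000122; adjusted p = 0.271 with an estimated correlation), but not without number 1 of the exercised group (adjusted p = 0.759; range over 8 alternatives 3.3e-12 to 0.759). Macrophage markers (Cd74 1.36, SE 0.46) and inflammation genes ranked higher, each at adjusted p = 0.00239 and at adjusted p = 0.179 with an estimated correlation; without number 2 of the exercised group the macrophage result did not pass (0.153; range over 8 alternatives 0.000403 to 0.179), and against the polysomal control Cd74 was at -0.49. Ribosomal protein genes ranked higher (adjusted p = 0.00284; adjusted p = 0.315 with an estimated correlation), but not without number 1 of the exercised group (0.601) or without array 2bA of the control (0.239; range over 8 alternatives 2.25e-05 to 0.601). Growth regulators ranked higher and the 19 glycolysis and glycogen genes lower, each at adjusted p = 0.0499 (0.295 and 0.179 as adjusted p with an estimated correlation). Neither passed after quantile normalization (0.067 and 0.124), with the 75th percentile (0.0779 for both), without array 2bA (0.0763 and 0.0942) or without number 2 of the exercised group (0.352 and 0.741), and the lowest adjusted p over the alternatives was 0.0359 and 0.0191.

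Polysomal against total RNA 6 h after exercise (4 numbers each) asks which transcripts were more or less represented on ribosomes than in the muscle as a whole. The endosomal GTPase Rab14 was 5.44-fold higher in polysomal RNA, at 1420 against 261 (log2 10.47 ± 0.46 and 8.03 ± 0.15, SD; adjusted p = 0.000434), and the glycolytic aldolase Aldoa 5.1-fold (log2 2.35, SE 0.39, adjusted p = 0.00403). Klf6 was higher by 2.32 (SE 0.49, adjusted p = 0.0114), the growth factor Pdgfa by 2.04 (SE 0.25, adjusted p = 0.00113) and the glucocorticoid receptor Nr3c1 by 1.85 (SE 0.31, adjusted p = 0.00403; 1 of its 2 probe sets). At the other end, Epn1, an adaptor of endocytosis, was at -1.95 (SE 0.31, adjusted p = 0.00377), the corepressor Tle5 at -1.84 (SE 0.29, adjusted p = 0.00325), the proteasome activator Psme4 at -1.64 (SE 0.34, adjusted p = 0.0102) and Myh7 at -1.47 (SE 0.28, adjusted p = 0.00646), the latter with signals of 3710 in polysomal and 10300 in total RNA.

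The test called 588 probe sets, 253 higher and 335 lower in polysomal RNA, with 366 genes among them (170 higher, 196 lower). Also among the 12 highest genes were Hist1h2af (2.03), Rps24 (1.99), Prkce (1.95), Fam162a (1.92), Wdfy1 (1.91), Mllt3 (1.87) and Plpp3 (1.74; 1 of its 2 probe sets). Also among the 12 lowest were Plagl1 (-1.63), Cyp2a1 (-1.54), Hspa4 (-1.50), Nrarp (-1.44), the mitochondrial carrier Ucp2 (-1.39), Vezf1 (-1.36), Dhx9 (-1.36) and Aplp2 (-1.33). Emc8 lay at the floor in total RNA and was at least 2.02-fold higher in polysomal RNA, and Gpam lay at the floor in polysomal RNA and was at least 1.65-fold higher in total RNA. The ratio of 3′ to 5′ signal of beta-actin also differed between fractions, at 2.54 to 4.48 on the polysomal arrays of 6 h against 1.01 to 1.58 on the total arrays of numbers 1, 2 and 4 and 9.01 to 11.5 on those of number 3. The middle of all probe sets lay at -0.163 under the deposited scaling and at -0.041 after quantile normalization, so lists are given relative to all genes. The split of calls moved with it, to 323 higher and 169 lower after quantile normalization, and to 330 and 160 with the 75th percentile.

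Of the 57 nuclear-encoded respiratory chain genes 14 were higher in polysomal RNA and none lower (17 and 0 when adjusted over the list alone), and the list lay 0.52 above all genes at the median. Among them were the cytochrome oxidase subunit Cox6c at 1.4 (SE 0.35), Atp5if1, the inhibitor of ATP synthase, at 1.39 (SE 0.23), and the complex I subunits Ndufa8 at 1.39 (SE 0.20, adjusted p = 0.00203) and Ndufc1 at 1.24 (SE 0.20, adjusted p = 0.00396). The list passed at adjusted p = 6.37e-09, and stood at adjusted p = 0.449 with an estimated correlation. Of 39 ribosomal protein genes 6 were higher and none lower (7 and 0 over the list alone), among them Rps24 at 1.99, Rpl17 at 1.39 (SE 0.26) and Rpl6 at 1.04 (SE 0.21). Of 34 proteolysis genes 4 were higher and 1 lower (5 and 1 over the list alone): the proteasome subunits Psma4 (1.13, SE 0.25) and Psmb3 (1.01, SE 0.24) were among the former, and the latter was the calcium-activated protease Capn1 (-0.85, SE 0.14). Ribosomal protein and proteolysis lists each passed at adjusted p = 0.000165, and each stood at adjusted p = 0.449 with an estimated correlation. After quantile normalization the ribosomal list did not pass (0.0668; range over 7 alternatives 4.7e-05 to 0.449).

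In lists that did not rank apart, single members differed. Among growth regulators Igfbp3, a binding protein of insulin-like growth factors, was higher (1.47, SE 0.28, adjusted p = 0.00764), but only 1 of its 2 probe sets had this direction. The transcription factor Mef2d (-0.83, SE 0.15) and the receptor Met (-0.80, SE 0.23) were lower. Of the antioxidant genes the extracellular superoxide dismutase Sod3 was lower (-1.33, SE 0.25) and the cytosolic Sod1 higher (0.97, SE 0.23). Nfkbia, the inhibitor of NF-kappa-B, was higher (1.51, SE 0.26), as was Amd1, an enzyme of polyamine synthesis (1.71, SE 0.41). Of the 22 heat shock and folding genes 2 were lower, the chaperones Canx at -1.02 (SE 0.23) and Hsp90b1 at -0.56 (SE 0.15), and the list did not pass (adjusted p = 0.552). Of the 31 matrix genes 4 were lower, including Sparc (-0.94, SE 0.24) and Bgn (-0.71, SE 0.17), and 1 was higher, Lox (1.73, SE 0.45), of whose 4 probe sets 2 had this direction. Among cell markers Fabp4 of adipocytes was higher (1.39, SE 0.38), and C1qc of macrophages (-0.60), Slc4a1 of red cells (-0.77, 2 of its 3 probe sets in this direction), Thbd of endothelium (-0.75) and Ngfr of nerve (-0.87) were lower. Lower too were the sarcomeric actinin Actn2 (-0.78, SE 0.23) and the elongation factor Eef1a2 (-1.07, SE 0.31). Some of these calls were weak: Actn2 passed in 6 of 22 alternatives, Met in 8 of 22, C1qc and Ngfr in 9 of 23 and Eef1a2 in 10 of 22. Igfbp3 and Nfkbia passed in 22 of 23. Each of these genes kept its direction in all alternatives.

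The 6 h total numbers were not alike. On an axis of 1086 probe sets that runs from 0 in numbers 1 and 2 of total RNA to 1 in their polysomal RNA, the 4 arrays of total numbers 3 and 4 lay at 0.75 to 0.79. Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, had signals of 3280 to 5110 on the total arrays of numbers 1 and 2 and of 130 to 147 on those of numbers 3 and 4, and its fraction difference of -2.42 (SE 0.94) did not pass (adjusted p = 0.116). Within numbers 1 and 2 alone 1086 probe sets were called, within numbers 3 and 4 alone 73, and 22 in both, and over all probe sets the differences of these pairs of numbers correlated at 0.225. The median absolute difference of the 588, chosen on all 4 numbers, was 0.961 and 0.924. Without both total numbers 3 and 4 there were 1468 calls. The count was 247, 285 and 355 without polysomal numbers 2, 3 and 4 and 1099 without total number 4.

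**Figure D2:**
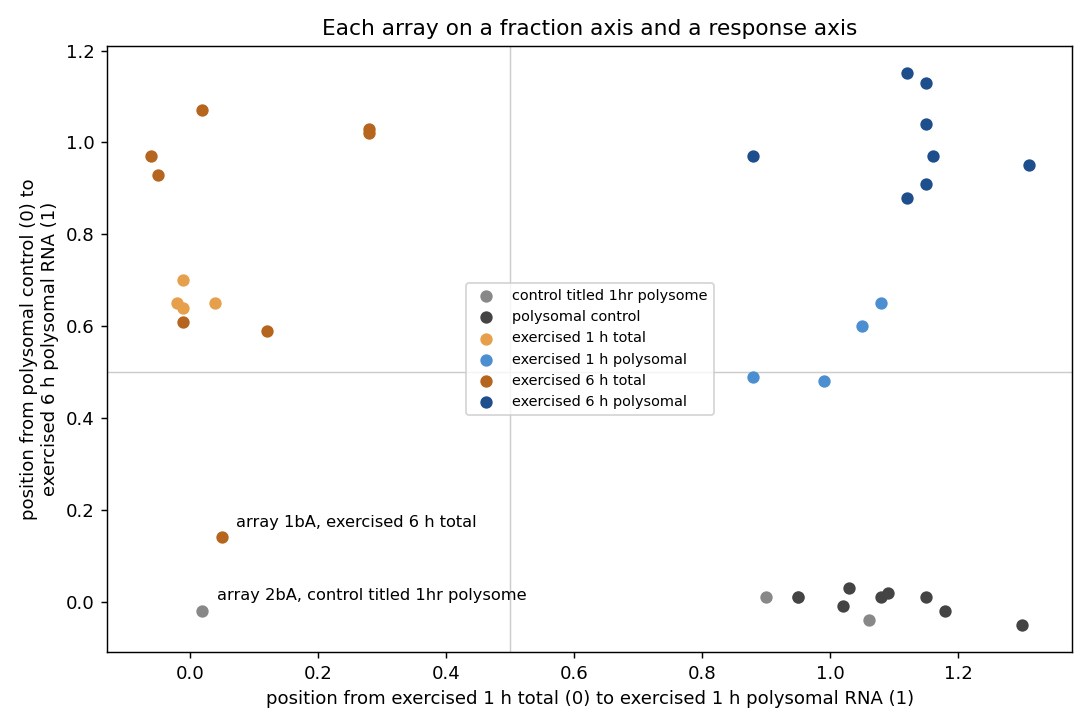
Position of each of the 36 arrays on an axis of RNA fraction (horizontal, 588 probe sets, 0 for total and 1 for polysomal RNA at 1 h) and an axis of the response to contractions (vertical, 23 probe sets, 0 for the polysomal control and 1 for polysomal RNA at 6 h). Array 2bA of the control titled 1hr polysome lies at 0.02 on the fraction axis, and array 1bA of the 6 h total group at 0.14 on the response axis.

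Polysomal against total RNA at 1 h (2 numbers each) gave 26 calls, 13 higher and 13 lower. By limma 1061 probe sets had an unadjusted p under 0.05, where chance gives 335, so the 26 are not all that may differ. The count rose without numbers 3 and 4 of the 6 h total group, which enter this comparison only through the shared spread. The secreted glycoprotein Fstl1 was higher in polysomal RNA by 2.13 (SE 0.33, adjusted p = 0.0224; 1 of its 2 probe sets), Rab14 by 2.02 (SE 0.35, adjusted p = 0.0343), P3h4 by 1.93 (SE 0.35) and Wdfy1 by 1.81 (SE 0.35), followed by Mtdh (1.58), the calcineurin subunit Ppp3ca (1.20) and the GTPase Rala (1.13). Chrna1, the muscle acetylcholine receptor alpha subunit, was at -4 (SE 0.63, adjusted p = 0.0224), at -5.31 without total number 1 and at -2.69 without total number 2 (adjusted p = 0.181); without polysomal number 2 the value was -3.89 (adjusted p = 0.165). Over all 16 alternatives its adjusted p reached at most 0.188. Also lower were Sod3 (-1.89, SE 0.35), Aplp2 (-1.61, SE 0.32), the elongin subunit Eloa (-1.42, SE 0.27), Supt5h (-1.4, SE 0.26, 2 of its 3 probe sets in this direction) and the cytosolic aconitase Aco1 (-1.37, SE 0.28). Supt5h passed in 10 of 16 alternatives, Sod3 and Aplp2 in 9, Eloa in 8 and Aco1 in 6, with Eloa at -1.63 to -0.24. The genes named as higher passed in 7 (Mtdh) to 12 (Fstl1) of 16. Myh7 (-1.82, SE 0.39, adjusted p = 0.0611), the slow fibre calcium pump Atp2a2 (-2.80, SE 0.61, adjusted p = 0.0661) and Gpd1 (-4.50, SE 1.32, adjusted p = 0.118) did not pass. The split was 21 higher and 18 lower after quantile normalization, and 18 and 10 with the 75th percentile.

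The beta-actin ratio of 3′ to 5′ signal was 2 to 4.28 on the polysomal and 1.22 to 1.62 on the total arrays of 1 h. The respiratory chain again ranked higher in polysomal RNA (median 0.62 above all genes, adjusted p = 2.18e-06; adjusted p = 0.462 with an estimated correlation), with none of the 57 genes passing by itself and 1 over the list alone. Slow fibre genes ranked lower (median -0.97, 4 of 10 lower and 1 higher over the list alone; adjusted p = 0.00685, and 0.257 as adjusted p with an estimated correlation), but not without polysomal number 2 (0.067; range over 7 alternatives 0.000138 to 0.257). Ribosomal protein genes ranked higher (adjusted p = 0.00748; adjusted p = 0.87 with an estimated correlation), but not after quantile normalization (0.79) or without polysomal number 1 (0.311; range over 7 alternatives 0.000303 to 0.87). The 32 fuel use and angiogenesis genes ranked lower (adjusted p = 0.0407; adjusted p = 0.304 with an estimated correlation), with 5 lower over the list alone, and did not pass without polysomal number 2 (0.329; range over 7 alternatives 0.000963 to 0.329). Each number weighed on the count of calls, which was 85 and 1 without polysomal numbers 1 and 2, and 15 and 1 without total numbers 1 and 2.

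The fraction differences at both times were compared on separate arrays. Of the 588 probe sets called at 6 h, 536 (91.2%) had the same sign at 1 h, against 68.3% of all probe sets, and all 26 called at 1 h had the same sign at 6 h. Called in both with the same sign were 19, where independent lists would share 2.3. The lists are not independent, since both tests use the same estimate of the spread of each probe set. Over all 6707 probe sets, which are not independent replicates, the correlation of both differences was 0.508. It was 0.655 with numbers 1 and 2 at 6 h alone and 0.128 with numbers 3 and 4 alone, where 72.6% of the 73 called and 59% of all probe sets had the same sign at 1 h.

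**Figure D3:**
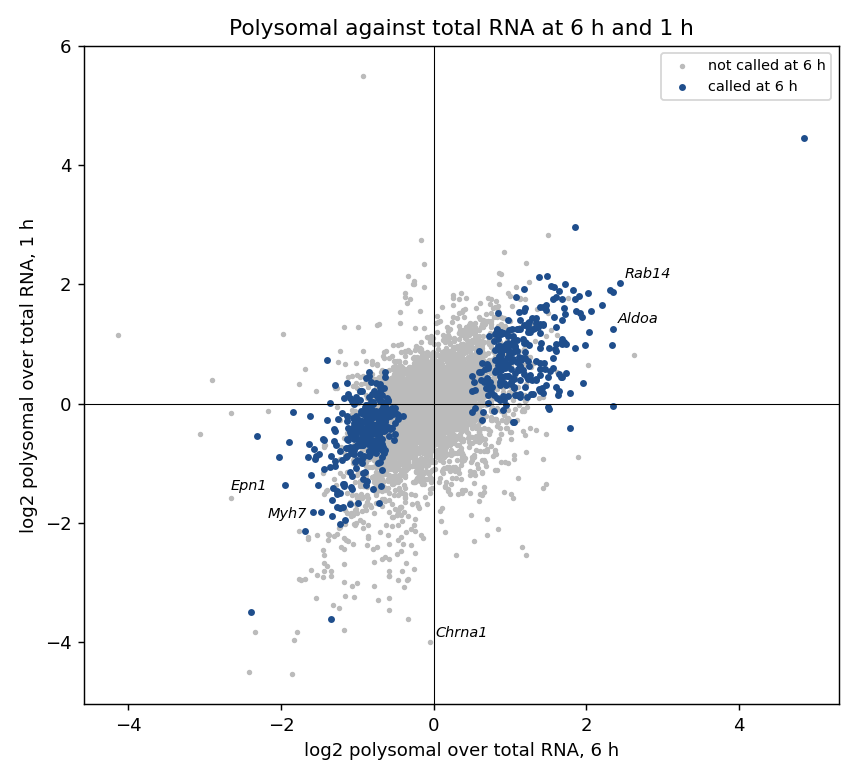
Log2 ratio of polysomal over total RNA of each tested probe set at 6 h (horizontal) and at 1 h (vertical), with the 588 probe sets called at 6 h in blue. Of these 536 have the same sign at both times; Rab14 lies at 2.44 and 2.02, Myh7 at -1.47 and -1.82, and Chrna1 lies at -4 at 1 h and near 0 at 6 h.

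In total RNA, 6 h was set against 1 h after contractions (4 and 2 numbers). Chrna1 fell by 3.56 on the log2 scale (SE 0.54, adjusted p = 0.0333), and both of the other named calls, probe sets of the embryonic myosin heavy chain Myh3 that were named after their values were seen, fell by 2.42 and 1.90; the brightest Myh3 probe set stood at -0.94 (adjusted p = 0.597). The delta subunit of the same receptor, Chrnd, stood at -2.29 (SE 0.50) and F3, the coagulation tissue factor, at -0.73 (SE 0.15), without passing, as did Pik3c3 (-0.65) and Maob (0.85). In all 4 probe sets were called, the last without a symbol, and no list passed. Under alternatives 5 lists passed with all probe sets of a gene, 2 after quantile normalization and 3 without numbers 3 and 4 of the 6 h total group, with matrix genes higher and ribosomal protein genes lower in each. The 1 h numbers differed in Chrna1, at 2790 for number 1 and 17100 for number 2; its change was -4.87 without number 1 and -2.25 without number 2 (adjusted p = 0.408), where 1 call was left. The count was 15 without 1 h number 1, 1 without each of the 6 h numbers 2, 3 and 4, and 7 without array 1bA of the 6 h group. The direction of calls turned with the 6 h numbers: without numbers 3 and 4 of the total group there were 22 higher and 3 lower, and with numbers 1 and 2 of the 6 h set alone 6 higher and 0 lower.

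In polysomal RNA, 6 h against 1 h (4 and 2 numbers) gave no call by limma, with 366 probe sets at an unadjusted p under 0.05. The smallest p-values were those of Phactr4 (-1.43, SE 0.28), Pelo (2, SE 0.39), Tuba4a (-0.84, SE 0.18), Vezf1 (-1.61, SE 0.37) and Ppp2r3a (1.26, SE 0.29), with adjusted p from 0.236 to 0.532. Slow fibre genes ranked higher at 6 h (median 0.47 above all genes, adjusted p = 0.00116; adjusted p = 0.0946 with an estimated correlation), although none of the 10 passed by itself or over the list alone; Myl2 stood at 1.07 (SE 0.38) and Tnni1, the slow troponin I, at 0.88 (SE 0.32). Without number 2 of the 1 h group the list did not pass (0.23; range over 6 alternatives 8.27e-06 to 0.23). Without numbers 1 and 2 of the 1 h group in turn there were 27 and 12 calls.

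The controls were compared with each other, the control titled 1hr polysome against the polysomal control (2 and 4 numbers). No probe set passed limma's test, with 367 at an unadjusted p under 0.05. Among probe sets with a symbol, the smallest p-values were those of the complement protease C1r (-1.36, SE 0.28), the endoplasmic reticulum protein P3h4 (-1.39, SE 0.30), the invariant chain Cd74 (-1.84, SE 0.40), Acp5 (-1.25, SE 0.28) and Mgp (-1.32, SE 0.31), with adjusted p from 0.316 to 0.346. Matrix genes ranked lower (median -0.47, adjusted p = 5.15e-05; adjusted p = 0.0939 with an estimated correlation), with 4 of 31 lower over the list alone and Lox at -1.90 (SE 0.55) and Mmp14, a matrix metalloproteinase, at -1.45 (SE 0.36). Antioxidant genes (adjusted p = 0.0121; adjusted p = 0.0939 with an estimated correlation) and proteolysis genes (adjusted p = 0.000186; adjusted p = 0.378 with an estimated correlation) ranked lower. All 18 fast fibre genes lay above 0 (median 0.63 above all genes, adjusted p = 0.000427; adjusted p = 0.378 with an estimated correlation), none passing by itself or over the list alone. On the fraction axis of 588 probe sets, array 2bA of the control titled 1hr polysome lay at 0.02 and its other 3 arrays at 0.90 to 1.06. Antioxidant genes did not pass without that array (0.0607) or with all probe sets of a gene (0.197; range over 5 alternatives 0.0203 to 0.197).

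Total RNA at 1 h was also set against the control titled 1hr polysome, so that the RNA fraction in the titles differs along with contraction (2 numbers each). Chrna1 was higher by 3.74 (SE 0.63, adjusted p = 0.0468), at 5.05 without total number 1 and at 2.43 without total number 2 (adjusted p = 0.257), and F3 lay at the floor in the control and was at least 1.97-fold higher (adjusted p = 0.0476). Of the 5 calls, all higher, 1 more was a probe set of Myh3 (3.22) and 1 of Junb (2.65), named after their values were seen, and the last had no symbol. Hspa1a (3.78, SE 0.72, adjusted p = 0.0811), Bcl2l2 (1.08), Fam32a (-1.30), Egr1 (3.88, SE 0.92) and Fos (3.43, SE 0.82) did not pass. Respiratory chain genes ranked lower (median -0.74, 50 of 57 below 0, adjusted p = 1.02e-12; adjusted p = 0.29 with an estimated correlation), with 2 lower over the list alone. Immediate early genes (adjusted p = 0.000315; 6 higher and 1 lower over the list alone) and growth regulators (adjusted p = 0.0182; 1 higher, or 5 higher and 1 lower over the list alone) ranked higher, each at adjusted p = 0.513 with an estimated correlation. Without array 2bA of the control there were 202 calls, with 107 lower, and growth regulators did not pass (0.104; range over 6 alternatives 0.00291 to 0.513). By limma the count was 0 without control number 1 or 2 (299 and 718 probe sets at an unadjusted p under 0.05), 19 without total number 1 and 1 without total number 2.

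Whether responses themselves changed with time was tested as differences of contrasts. The fraction difference at 6 h minus that at 1 h gave no call by limma, with 372 probe sets at an unadjusted p under 0.05. Chrna1 had the smallest p (3.96, SE 0.77, adjusted p = 0.417), followed by Tuba4a (-1.17), Pcsk2 (-1.07), Ruvbl1 (1.41) and Ghr, the growth hormone receptor (-2.04). For Ruvbl1 1 of 2 probe sets had this direction, and for Ghr 2 of 3. Slow fibre genes were relatively higher in polysomal RNA at 6 h than at 1 h (median 0.89, adjusted p = 0.00171; adjusted p = 0.109 with an estimated correlation), with Casq2, the cardiac and slow fibre calsequestrin, at 1.45 (SE 0.54). Fuel use genes were higher as well (median 0.34, adjusted p = 0.0401; adjusted p = 0.205 with an estimated correlation). No gene of either list passed by itself or over the list alone. Without number 2 of the 1 h polysomal group neither list passed (0.128 and 0.314), and without numbers 3 and 4 of the 6 h total group the fuel use list did not (0.197). Over 9 alternatives each, adjusted p ran from 1.08e-05 to 0.128 for slow fibre genes and from 0.00142 to 0.314 for fuel use. Single probe sets were called when 1 h numbers were left out, 14 without polysomal number 1, and 8 and 1 without total numbers 1 and 2.

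The polysomal response at 6 h minus that at 1 h gave no call by limma either, with 173 probe sets at an unadjusted p under 0.05. The smallest p-values belonged to Kif13a (1.43, SE 0.40), Ncr3 (1.06), Asb1 (1.12), Arl10 (-0.99) and Slc22a7 (-1.44), all at adjusted p = 1. Slow fibre genes ranked higher (median 0.95, 9 of 10 above 0, adjusted p = 9.33e-06), the only list result of the 10 comparisons to pass with an estimated correlation (adjusted p = 0.0192). The difference was 1.17 for Myh7 (SE 0.48), 1.32 for Myl2 (SE 0.54), 1.11 for Tnni1 (SE 0.46) and 1.65 for Atp2a2 (SE 0.75), none passing by itself or over the list alone. By fry, which asks whether the genes of a list move on balance one way, the slow fibre result did not pass (adjusted p = 0.0798). Of the 35 list results that passed with camera, 3 passed with fry: slow fibre genes in the polysomal response at 1 h (adjusted p = 0.0491), and slow fibre (0.0155) and fuel use genes (0.0264) in the fraction difference at 1 h. These 3, and every slow fibre result that passed with camera, share the arrays of exercised 1 h polysomal RNA. Matrix genes ranked lower (median -0.42, adjusted p = 0.00754; adjusted p = 0.212 with an estimated correlation), with Mgp at -1.04 (SE 0.44) and Sparc at -0.98 (SE 0.42). These differences are the sum of that between the exercised groups and that between the controls. For matrix genes the former had a median of 0.05 above all genes (adjusted p = 0.462) and the latter one of -0.47, with Mgp at 0.28 and -1.32; for slow fibre genes the medians were 0.47 and 0.30. Without number 2 of the 1 h polysomal group the slow fibre result stood at adjusted p = 0.0327 and that of the matrix at adjusted p = 0.648, and over all alternatives the slow fibre result ran from 4.35e-07 to 0.0327. For the matrix the range was 0.000306 to 0.648. Without number 1 of that group 17 probe sets were called.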

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

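Of the tests below, the 2 counts of sample splits and the position of both replicates of the control titled 1hr polysome were written before their results were seen. Those of array 2bA, of numbers 3 and 4 of the 6 h total group and of array 1bA were chosen only after.

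Single numbers far from the others of their group were looked for in 235 groups of 4 numbers, for the genes named above and some others, such as Lamc1. In 16 of them the gap of the end value to its neighbour, over the range of the group, exceeded Dixon's critical value, where chance gives about 12. In the 6 h total group, number 3 lay apart for Fam162a (0.909), Nr3c1 (0.878), Cox6c (0.914) and Sod1 (0.84), number 4 for Ngfr (0.887) and number 1 for Pik3c3 (1). In 6 h polysomal RNA, number 1 lay apart for Nfkbia (0.841), Amd1 (0.862), Ghr (0.9) and Lamc1 (0.843), number 2 for Psme4 (0.844) and Gpd1 (1), and number 4 for Klf6 (0.867), Asb1 (0.856) and Met (0.833). In the polysomal control number 4 lay apart for Hbegf (0.973). For Pik3c3 and Gpd1 the gap fills the whole range, because the other numbers of the group all lay at the floor.

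Whether an effect differed between times was tested as a difference of contrasts, and 4 list results passed. All 4 use the same arrays of exercised 1 h polysomal RNA (2 numbers), as do the other slow fibre results that passed. They are therefore not separate findings. The change of the polysomal against total difference from 1 h to 6 h passed for slow fibre genes (adjusted p = 0.00171) and for fuel use genes (adjusted p = 0.0401), and the polysomal response differed between 6 h and 1 h for slow fibre genes (adjusted p = 9.33e-06) and for matrix genes (adjusted p = 0.00754). Of these 4, all but the slow fibre result of the polysomal response (adjusted p = 0.0192) did not pass with an estimated correlation or without number 2 of the 1 h polysomal group. The difference is the sum of that between the controls and that between the exercised groups, whose medians against all genes were -0.47 and 0.05 for matrix genes and 0.30 and 0.47 for slow fibre genes.

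The RNA fraction of the control titled 1hr polysome is given differently by its title and its description. On the axis from total (0) to polysomal RNA (1) at 1 h, its replicates lay at 0.93 and 0.54, both above the 0.5 set in the test written before, which goes with the title and not with total RNA in the whole group. Looked at singly afterwards, 3 of its arrays lay at 0.90 to 1.06 and array 2bA at 0.02, which goes against polysomal RNA on 2bA. That position is also the observation that raised the question. As a separate measure, the beta-actin ratio of 3′ to 5′ signal was 1.07 on 2bA and 1.99 to 2.73 on the other 3 arrays. The Gapdh ratio of 2bA, 0.513, lay within the range of other polysomal arrays. Total RNA on array 2bA alone (0.02) is a candidate explanation, and without this array the 1 h total comparison gave 202 calls in place of 5. No biological explanation was tested.

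Numbers 3 and 4 of the 6 h total group lay apart from numbers 1 and 2 on the fraction axis of the 6 h set. Polysomal RNA on their arrays is not excluded there, since their highest array reached 0.79 and the lowest of all polysomal groups without 2bA 0.82. On an axis of the 26 probe sets called at 1 h they lay at 0.46 to 0.56, with total numbers 1 and 2 at 0.33 to 0.36 and 6 h polysomal RNA at 0.82 to 1.05. That test asked whether all 4 arrays lay above or below 0.5. They lay on both sides, so it did not decide. By the beta-actin ratio of 3′ to 5′ signal alone, number 4 lay apart from polysomal RNA. It was 1.09 to 1.25 there, against 1.58 to 4.48 on the polysomal arrays of the exercised groups and the polysomal control. The Gapdh ratio did not separate the fractions. It was 0.538 to 0.857 on number 4, with 0.0374 to 1.3 on those polysomal arrays. On the total arrays of 1 h and of numbers 1 and 2 at 6 h it was 0.53 to 1.09. The fraction of number 4 thus stays open. Partly degraded RNA remains a candidate explanation for number 3, whose lower ratio of 3′ to 5′ signal of beta-actin was 9.01 against at most 4.48 on the other arrays, but not for number 4, whose lower ratio was 1.09. The design gives no group that separates these numbers, and no biological explanation was tested.

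Array 1bA of the 6 h total group lay at 0.14 on the axis of the polysomal response at 6 h, while its partner, 1A, lay at 0.93. RNA of muscle that was not contracted may be on this array. Its position fits this hypothesis, but is also the observation that raised it, and so lends no separate support. A swap with an array of either control group of this series is excluded, since the highest control array lay at 0.03. An exchange with an array outside the series could not be tested. Without 1bA the 6 h against 1 h comparison of total RNA gave 7 calls in place of 4. No biological explanation was tested.

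For polysomal RNA at 6 h against its control, 2 of the 35 splits of the 8 numbers into groups of 4 gave as many calls as the real 23, the real one included, and by this count chance is not excluded. These splits disregard the likeness of equal numbers. The highest other, with 127 calls, parts numbers 1 and 2 from numbers 3 and 4, which points to a structure of the samples. Among the 8 splits that part all 4 pairs of equal numbers, as the real one does, the highest other gave 0 calls. But 8 splits are too few for a share under 0.05. For polysomal against total RNA at 6 h, 1 of the 35 splits, the real one, gave as many as 588, a share under 0.05. By the rule written before, this goes against chance. These splits again disregard the likeness of equal numbers, which limits that reading. The highest other, with 166 calls, again parts numbers 1 and 2 from numbers 3 and 4. Among the 8 splits that part all 4 pairs the highest other gave 0 calls. But 8 are too few for a share under 0.05, so this set could not exclude chance whatever its outcome.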

How the results depend on the processing

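The counts of calls are given by alternative, each against the reported 23 and 0 (polysomal response at 6 h and 1 h), 588 and 26 (fraction difference at 6 h and 1 h), 4 and 0 (6 h against 1 h in total and polysomal RNA), 0 (both controls) and 5 (1 h total RNA against the control titled 1hr polysome), and 0 and 0 (changes of the fraction difference and of the response). The cause of a changed count was not tested, except that fewer samples, fewer probe sets or more entries are part of an alternative's construction.

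A floor at the 20th percentile gave 9 calls for the 1 h fraction difference, and by limma 0 for 6 h against 1 h in total RNA and 0 for 1 h total RNA against control (606 and 838 at an unadjusted p under 0.05). A floor at the 60th percentile gave 41 for the 1 h fraction difference and 1 for 6 h against 1 h in polysomal RNA. Without a filter on dim probe sets there were 8 for the 6 h response, 390 for the 6 h fraction difference, 11 for total RNA over time, 10 for 1 h total RNA against control and 3 for the change of the fraction difference. Arrays entered singly gave 106 and 4 for the responses, 364 for the 1 h fraction difference, 20 and 6 over time, 15 between controls, 113 for 1 h total RNA against control and 2 for the change of the fraction difference. Only the groups of a comparison gave 62 for the 6 h response, 128 and 45 for the fraction differences, and by limma 0 for total RNA over time and 0 for 1 h total RNA against control (266 and 1369 at an unadjusted p under 0.05). A variance trend with robust estimation gave 8 for 1 h total RNA against control, and both controls together gave 46 for the 6 h response.

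Equal numbers as a replicate block gave 120 for the 1 h fraction difference and 30 for 1 h total RNA against control. The block brought every other count within 1.5 times its value (33 for the 6 h response, with 22 of the 23 among them, 693 for the 6 h fraction difference). The deviations of equal numbers correlated from 0.073 to 0.25 between 6 h polysomal and total RNA, and 3 of the 4 correlated best with their own number.

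The runs in this paragraph were chosen after seeing the data. Without array 2bA, 1 h total RNA against control gave 202, and without array 1bA total RNA over time gave 7. Numbers 1 and 2 of the 6 h set alone gave 1 for the 6 h response, 1086 for the 6 h fraction difference, 60 for polysomal RNA over time and 105 between controls; total RNA over time gave 6, all higher, where the reported 4 were all lower. Numbers 3 and 4 alone gave by limma 0 for the 6 h response (424 at an unadjusted p under 0.05), 73 for the 6 h fraction difference, 585 for total RNA over time and 128 for the change of the fraction difference. Without numbers 3 and 4 of the 6 h total group there were 52 for the 6 h response, 1468 and 596 for the fraction differences, 25 for total RNA over time (22 higher and 3 lower), 1 between controls, 325 for 1 h total RNA against control and 2 for the change of the fraction difference; in comparisons that do not hold this group, only the spread that all groups share in the fit changed. Without the arrays named 1A and 2A there were 5 for the 6 h response, 4 for the 1 h fraction difference and 2 for total RNA over time. On those of 6 h polysomal RNA and of the polysomal control, 0 to 10 probe sets exceeded a signal of 20000. The other arrays of these groups had 24 to 142. Without probe sets above 20000 there were 8 for the 6 h response.

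With each number left out in turn, counts ran from 7 to 38 and from 0 to 46 for the responses, 247 to 1099 and 1 to 85 for the fraction differences, 1 to 15 and 0 to 27 over time, 0 to 0 between controls, 0 to 19 for 1 h total RNA against control, 0 to 14 for the change of the fraction difference and 0 to 17 for that of the response. Where 1 number was left in a group, it was assumed to vary like those of the other groups.

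Of the 220 list tests 35 passed, 1 with an estimated correlation and 54 with all probe sets of a gene. For 198 results of named genes and some others, 4229 alternative values were computed: 3477 kept direction and side of the threshold, 595 kept direction and no longer passed, 152 kept direction and passed, 5 uncalled values changed sign and none that was called did. Signal over background limits dim genes: from 32.9% to 47.2% of an array's values lay at the floor, where a change is not measurable.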
